A study of Oryctolagus cuniculus with 9 samples.

How the data were processed

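The analysis started from a deposited table of 23669 genes with counts and FPKM for each of the 9 libraries. The counts were deposited as whole numbers per gene and library, and the FPKM were deposited as values per kilobase of gene and per total count, as read from the column names. Recomputing gene length from count and FPKM gave the same length in every library within 4.5e-05 (relative) over 9796 genes, so the FPKM hold no scaling beyond total count and length. According to the labels, RNA was extracted with Trizol and 1 ug of total RNA went into each TruSeq RNA library. Bowtie 0.12.2 and the build OryCun2.0 are named without a role. The steps between reads and counts, the counting tool, the annotation release and the strand protocol are not given in the sources used here. Without the strand, overlapping antisense transcripts cannot be separated, and counts at loci with close paralogs may be shared between them. Names came from the table for 14194 genes, from a RefSeq accession for 34 and from a gene description for 3, and 9438 genes had none. In all, 8154 genes had no count in any library.

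Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 11291 genes, 9107 of them named. Counts were scaled by TMM and fitted with the quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, robust, with 1 coefficient per group and all 9 libraries in the fit (6 residual degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and genes under 0.05 were called. SE were derived from the test, as the absolute fitted log2 change divided by the square root of its F statistic. Fold changes are the fitted ones, so they can differ from the ratio of mean CPM.

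Gene lists were fixed before the values were seen, 39 in number with 1003 symbols, of which 786 matched the table. Lists with at least 5 tested members, 33 in all, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the 33 lists, and 6 lists had too few. Individual members were also adjusted over their own list alone. Named genes were chosen by rule. These were the 8 genes per direction with the largest log2 change among those with a symbol, adjusted p under 0.05, groups that did not overlap and a mean of at least 5 FPKM in the higher group. To these were added the 3 members with the smallest p from each list that camera called or that had at least 3 members past the test, and 8 osteoblast markers fixed beforehand, with at most 2 unnamed genes per direction. Other named list members were chosen after their values were seen and were not run through the alternatives.

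Alternatives were DESeq2 1.42.0, its size factors in edgeR, library size alone, limma on log2(FPKM + 1), no filter, at least 50 counts in 3 libraries, only the 6 libraries compared, replicate number as a block, each library left out in turn, a log2 change of at least 1, adjusted p under 0.01, camera with an estimated correlation, and fry. Added after the values were seen were a fit without CS replicate 2 and M-CS replicate 1 and a comparison with the mean of CS and M-CS. Replicate number was not used as a block in the main model. Of 9 pairs of libraries sharing a number, 2 correlated above 0.1 after removal of group means (range -0.17 to 0.29), and 6 of 9 libraries correlated best with a library of their own number. The pairs that held a 5% CBM-CS library correlated at 0.01 to 0.041. These values do not settle whether the numbers pair the libraries. With the block, 2087 genes passed for 5% CBM-CS against CS in place of 1802, and 1673 against M-CS in place of 1455. For groups with few counts the floor was 3 counts over the group, or 0.0835, 0.0866 and 0.0878 CPM in CS, M-CS and 5% CBM-CS.

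Counts were simulated from the mean CPM of each gene over all libraries and 1 fitted spread per gene, with 50 genes changed at each of 4 folds. For 5% CBM-CS against CS, edgeR found 30%, 62%, 92% and 98% of genes changed 1.25, 1.5, 2 and 4-fold, and 9.14% of its calls were false. For 5% CBM-CS against M-CS it found 22%, 58%, 84% and 94%, with 5.3% false, and for M-CS against CS 18%, 62%, 86% and 100%, with 3.27% false. Camera called the planted list of 20 genes changed 1.5-fold in each comparison and no other simulated list. The simulated genes were drawn independently of one another, so this does not test how correlation between genes affects the list calls.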

Results

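RNA sequencing measured gene expression in rabbit bone marrow mesenchymal stem cells (rBMSCs), the stromal progenitors of bone marrow, taken from New Zealand White animals aged 8 weeks. The cells grew on calcium silicate scaffolds and were released with trypsin before RNA extraction. There were 3 groups of 3 libraries. CS denotes untreated scaffolds, M-CS scaffolds treated with medium, and 5% CBM-CS scaffolds treated with 5% bacteria medium. Total counts in CS replicates 1, 2 and 3 were 11.35 M, 11.79 M and 11.8 M. They were 10.6 M, 12.01 M and 11.53 M in M-CS, and 12.82 M, 11.1 M and 11.78 M in 5% CBM-CS. Group values are given as mean ± SD over 3 libraries, in CPM, counts scaled by TMM to a common library size. Positions are those given in the deposited table, and the labels name the rabbit genome build OryCun2.0. The labels do not say that the replicates came from separate cultures or animals, so every p-value measures the spread between these libraries, which may be technical.

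The 5% CBM-CS libraries lay apart from the other 6 on the first principal component, which held 43.1% of the variance. The other 6 did not separate by group. CS replicate 1, CS replicate 3 and M-CS replicate 1 lay together, and CS replicate 2, M-CS replicate 2 and M-CS replicate 3 lay together. These 2 sets were apart on the first component and on the second, which held 15.4%. Correlations of log2 CPM between CS and M-CS libraries ranged from 0.9868 to 0.9926, against 0.9869 to 0.9906 within CS and 0.9874 to 0.9922 within M-CS. Those between 5% CBM-CS and the other groups ranged from 0.9754 to 0.983. CS replicate 2, M-CS replicate 2 and M-CS replicate 3 lay nearer to 5% CBM-CS for several genes that differed between the groups. For CSF2 they had 20.5 to 23.8 CPM, where CS replicate 1, CS replicate 3 and M-CS replicate 1 had 4.37 to 6.31 CPM and 5% CBM-CS had 162 to 174 CPM. The 10 most abundant genes took 15.47 ± 0.813% of the counts in CS, 15.91 ± 0.508% in M-CS and 21.42 ± 0.553% in 5% CBM-CS. Mitochondrial transcripts took 4.793% to 5.099% in every library.

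**Figure D1:**
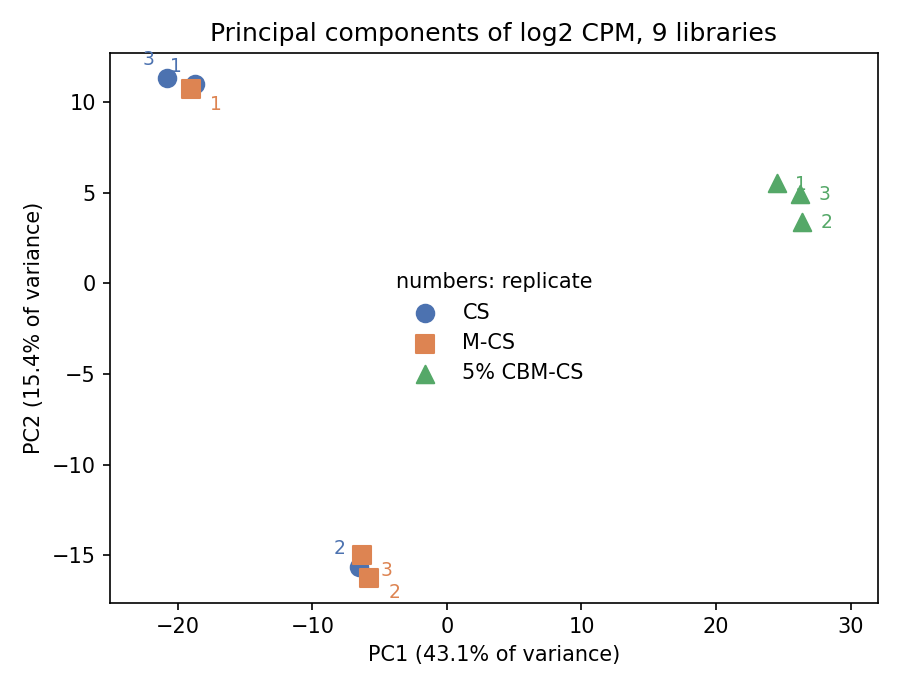
First and second principal components of log2 CPM (axis units are component scores) for 9 libraries, with group shown by symbol and replicate by number. The 3 libraries of 5% CBM-CS lie together, and the CS and M-CS libraries form 2 clusters that each hold both groups.

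The comparison of 5% CBM-CS with CS asked how rBMSCs on scaffolds treated with bacteria medium differed from those on untreated scaffolds. Among genes with at least 5 FPKM in the higher group, cytokine genes showed the largest rises. IL36G, a cytokine of the interleukin-1 family (ENSOCUG00000006660, chromosome 2, 97749486 to 97756304), rose from 10.6 ± 1.13 to 198 ± 10.4 CPM (log2 change 4.23, SE 0.09, adjusted p = 1.1e-15), and its neighbour IL36A (ENSOCUG00000014998, chromosome 2, 97773226 to 97777970) rose from 3.98 ± 0.545 to 47.0 ± 2.88 CPM (log2 change 3.56, SE 0.15, adjusted p = 4.9e-11). Genes that fell included PHGDH, the first enzyme of serine synthesis (46.1 ± 3.54 against 90.6 ± 3.36 CPM), HMGCS1 of the mevalonate pathway (103 ± 2.01 against 165 ± 10.1 CPM) and LOX, which cross-links collagen (1122 ± 27.5 against 1976 ± 35.7 CPM). Of 11291 genes tested with edgeR, 1802 passed, 897 higher and 905 lower in 5% CBM-CS, and 264 of them differed by at least 2-fold. Of the 1802 genes, 230 had no name. The 3 values of each group did not overlap in 33.9% of tested genes, where chance gives 10%.

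Among the other genes with the largest rises, CSF2, which encodes the growth factor GM-CSF (ENSOCUG00000003433, chromosome 3, 15143063 to 15146030), rose from 9.97 ± 9.09 to 169 ± 6.06 CPM (log2 change 4.09, SE 0.62, adjusted p = 0.0068). IL23A, a subunit of interleukin-23 (ENSOCUG00000007233, chromosome 4, 39913661 to 39916220), rose from 24.0 ± 15.3 to 294 ± 7.29 CPM (log2 change 3.62, SE 0.52, adjusted p = 0.0055). The chemokine CCL5 (ENSOCUG00000002848, chromosome 19, 24922478 to 24932917) rose from 11.4 ± 9.28 to 109 ± 3.41 CPM (log2 change 3.26, SE 0.57, adjusted p = 0.012), and the call was lost (adjusted p = 0.0504 without CS replicate 1). The macrophage elastase MMP12 (ENSOCUG00000008303, chromosome 1, 113690095 to 113701956) rose from 61.4 ± 11.5 to 429.9 ± 6.80 CPM (log2 change 2.81, SE 0.12, adjusted p = 3e-08), VSIG4 (ENSOCUG00000004172, chromosome X, 44499066 to 44569353) from 2.18 ± 1.24 to 15.04 ± 1.34 CPM and the xenobiotic-metabolising CYP1A1 (ENSOCUG00000017744, scaffold GL019033, 237281 to 242756) from 10.1 ± 0.996 to 67.7 ± 2.79 CPM (log2 change 2.75, SE 0.11, adjusted p = 4.2e-11). Rises and falls were ranked among genes with a symbol, groups that did not overlap and at least 5 FPKM in the higher group. By this rule the largest falls were in DERL3, of endoplasmic reticulum protein degradation (ENSOCUG00000026022, scaffold GL019236, 89984 to 91812, 0.142 ± 0.133 against 3.60 ± 0.857 CPM, log2 change -4.52, SE 0.50, adjusted p = 8.6e-06), and the adhesion molecule NCAM1 (ENSOCUG00000006190, chromosome 1, 103075145 to 103403709, 30.4 ± 1.49 against 139 ± 48.9 CPM, log2 change -2.20, SE 0.40, adjusted p = 0.014). The DERL3 mean in 5% CBM-CS lay near the floor of 0.0878 CPM (3 counts over the group), so the size of its fall is poorly determined. ALDH1L2, of mitochondrial folate metabolism (ENSOCUG00000006962, chromosome 4, 91263358 to 91325818), fell from 112 ± 33.9 to 30.03 ± 2.71 CPM (log2 change -1.90, adjusted p = 0.024). Leaving out 1 library ended the calls of NCAM1 (adjusted p = 0.0531 to 0.0562 without 5% CBM-CS replicate 1, 2 or 3) and ALDH1L2 (adjusted p = 0.0701 to 0.0867 without CS replicate 1 or 3 or 5% CBM-CS replicate 1, 2 or 3). SH3BGRL2 (3.42-fold, adjusted p = 6.6e-06), IGSF10 (3.41-fold, adjusted p = 0.0014), KCNN4 (2.80-fold, adjusted p = 2.7e-05), XYLT1 (2.78-fold, adjusted p = 0.00063) and TMEM100 (2.73-fold, adjusted p = 4.8e-06) were also lower. Of genes without a name under the same cuts, ENSOCUG00000029216 (2.17 on the log2 scale) and ENSOCUG00000011609 (1.93) rose most, and ENSOCUG00000000779 (-1.75) and ENSOCUG00000027176 (-1.43) fell most. CSF2, CCL5, IL23A, NCAM1 and ALDH1L2 took values between those of the other libraries in CS replicate 2, as in M-CS replicates 2 and 3, with 41.6 CPM of IL23A against 15.1 and 15.2 CPM in CS replicates 1 and 3, and 83.1 CPM of NCAM1 against 163 and 172 CPM.

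**Figure D2:**
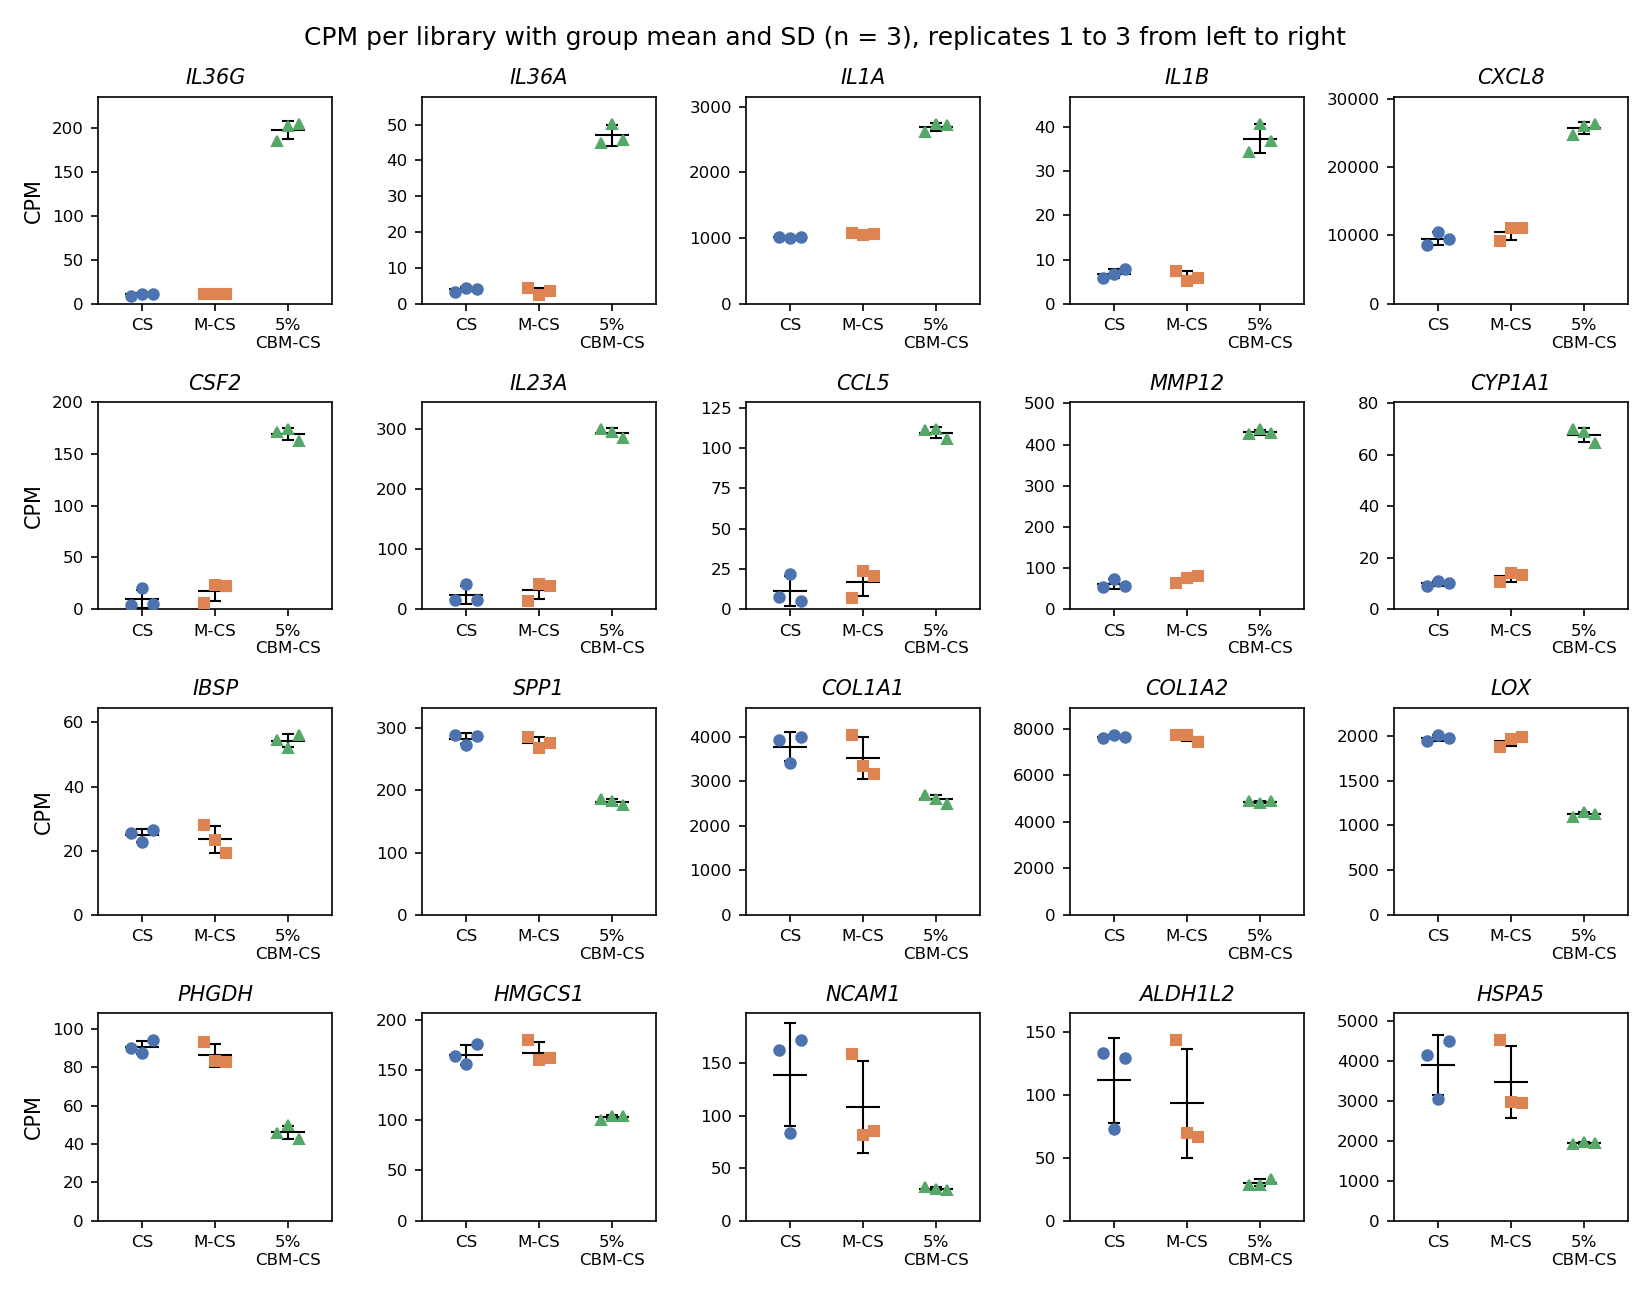
CPM of 20 genes in each library (points, replicates 1 to 3 from left to right) with group mean and SD bars (n = 3), each panel on its own linear axis from 0. IL36G reached 198 CPM in 5% CBM-CS against 10.6 in CS, and PHGDH fell to 46.1 from 90.6 CPM.

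Of 16 tested inflammatory cytokines and chemokines, 11 rose, 1 fell and 4 did not pass the test (12 and 1 adjusted over the list alone). The list's median log2 change was 1.00. As a list, inflammatory cytokines had camera adjusted p = 3e-08, and adjusted p = 0.13 with an estimated correlation. IL1A rose from 1013 ± 10.3 to 2694 ± 68.4 CPM (log2 change 1.41, SE 0.06, adjusted p = 4.2e-11), IL1B from 6.76 ± 1.04 to 37.4 ± 3.28 CPM (log2 change 2.46, SE 0.14, adjusted p = 2.7e-09) and the neutrophil chemokine CXCL8 from 9515 ± 929 to 25689 ± 879 CPM (log2 change 1.43, SE 0.09, adjusted p = 6.5e-09). TNFAIP6, which binds hyaluronan, was the member that fell (adjusted p = 0.0017). Of 29 genes of bacterial sensing and NF-kB response, 14 rose, 0 fell and 15 did not pass the test (17 and 0 adjusted over the list alone). As a list, NF-kB genes had camera adjusted p = 9.4e-08, and adjusted p = 0.14 with an estimated correlation. Members that rose included the apoptosis inhibitor BIRC3 (2.18-fold, adjusted p = 9.2e-10), the Toll-like receptor adaptor IRAK2 (1.94-fold, adjusted p = 1.4e-06) and the NF-kB inhibitor NFKBIE (1.75-fold, adjusted p = 1.4e-05). Of 24 interferon response genes, 8 rose, 0 fell and 16 did not pass the test (9 and 0 adjusted over the list alone). As a list, interferon genes had camera adjusted p = 5.6e-06, and adjusted p = 0.47 with an estimated correlation. The transcription factors IRF1 (2.31-fold, adjusted p = 1e-05) and IRF7 (2.25-fold, adjusted p = 0.00022) rose, as did the immunoproteasome subunit PSMB8 (3.45-fold, adjusted p = 3.6e-05). In the interferon list MX1 did not pass (adjusted p = 0.3). It had 32.9 CPM in CS replicate 2 against 13.1 and 10.4 CPM in CS replicates 1 and 3, and IRF1 had 35.2 against 25.0 and 25.6 CPM.

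Of 21 genes of the NRF2 and metal response, 12 rose, 0 fell and 9 did not pass the test (14 and 1 adjusted over the list alone), with a median log2 change of 0.37. As a list, NRF2 genes had camera adjusted p = 4.9e-07, and adjusted p = 0.017 with an estimated correlation. GCLM (2.02-fold, adjusted p = 1.2e-05), a subunit of the enzyme that starts glutathione synthesis, the peroxidase PRDX1 (1.495-fold, adjusted p = 2.3e-05) and the glutathione reductase GSR (1.39-fold, adjusted p = 8.9e-05) were the 3 with the smallest p. Of 18 nuclear-encoded respiratory chain genes, 4 rose, 0 fell and 14 did not pass the test (6 and 0 adjusted over the list alone). As a list, respiratory chain genes had camera adjusted p = 0.00027, and adjusted p = 0.27 with an estimated correlation. COX5B, a subunit of cytochrome c oxidase, rose from 104 ± 6.43 to 130.0 ± 2.27 CPM (adjusted p = 0.0018). NDUFA2 and ATP5C1 also passed (adjusted p = 0.015 and 0.023), and leaving out 1 library ended the calls of NDUFA2 (adjusted p = 0.0564 to 0.081 without CS replicate 1 or 5% CBM-CS replicate 2 or 3) and ATP5C1 (adjusted p = 0.0807 to 0.0897 without CS replicate 1 or 3 or 5% CBM-CS replicate 2 or 3).

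Of 27 genes of the integrated stress response and amino acid synthesis, 2 rose, 17 fell and 8 did not pass the test (2 and 19 adjusted over the list alone, median log2 change -0.50). As a list, integrated stress genes had camera adjusted p = 8.4e-08, and adjusted p = 0.14 with an estimated correlation. PHGDH fell by 0.98 on the log2 scale (adjusted p = 1.5e-07), and the folate enzyme MTHFD2 (1.72-fold, adjusted p = 2.3e-07) and the stress sensor SESN2 (2.21-fold, adjusted p = 2.6e-07) fell with it. Of 22 genes of the unfolded protein response and ER chaperones, 1 rose, 6 fell and 15 did not pass the test (1 and 12 adjusted over the list alone, median log2 change -0.49). As a list, unfolded protein genes had camera adjusted p = 2.3e-05, and adjusted p = 0.48 with an estimated correlation. HERPUD1 (1.48-fold, adjusted p = 3.4e-05) and the sensor ATF6 (1.37-fold, adjusted p = 0.012) fell, and the transcription factor XBP1 (1.31-fold, adjusted p = 0.0035) rose. The ATF6 call was lost (adjusted p = 0.0543 to 0.056 without CS replicate 1 or 3 or 5% CBM-CS replicate 3). The chaperone HSPA5, another member, fell from 3889.5 ± 756 to 1933 ± 19.7 CPM (adjusted p = 0.015). It had 3040.1 CPM in CS replicate 2 against 4139 and 4489 CPM in CS replicates 1 and 3. Of 19 cholesterol synthesis genes, 0 rose, 11 fell and 8 did not pass the test (0 and 12 adjusted over the list alone, median log2 change -0.28). As a list, cholesterol genes had camera adjusted p = 3.8e-07, and adjusted p = 0.017 with an estimated correlation. HMGCS1 (log2 change -0.68, SE 0.07, adjusted p = 1.9e-06) and CYP51A1 (1.41-fold, adjusted p = 0.00013) were among those that fell.

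Of 20 collagens, 3 rose, 9 fell and 8 did not pass the test (4 and 13 adjusted over the list alone). As a list, collagens had camera adjusted p = 0.0024, and adjusted p = 0.23 with an estimated correlation. COL11A1 and COL1A2 fell (270.5 ± 3.30 against 456 ± 14.3 CPM, and 4858 ± 43.1 against 7652 ± 74.2 CPM), with adjusted p = 1.6e-07 and 6.7e-07, whereas COL7A1 (2.16-fold, adjusted p = 8.6e-07) rose. Of 31 non-collagen matrix glycoproteins and proteoglycans, 3 rose, 15 fell and 13 did not pass the test (4 and 17 adjusted over the list alone). As a list, matrix glycoproteins had camera adjusted p = 0.00027, and adjusted p = 0.33 with an estimated correlation. LOX, POSTN (1.73-fold, adjusted p = 4.2e-07) and the microfibril protein FBN1 (1.49-fold, adjusted p = 3e-06) were lower. Of 10 chondrocyte genes, 0 rose, 4 fell and 6 did not pass the test (0 and 5 adjusted over the list alone). As a list, chondrocyte genes had camera adjusted p = 0.0041, and adjusted p = 0.17 with an estimated correlation. The cartilage transcription factor SOX9 (1.62-fold, adjusted p = 0.00021) and ACAN (1.502-fold, adjusted p = 4.1e-05) were among those lower. COL11A1 is on the collagen list as well as the chondrocyte list, and ACAN is on the matrix list as well. These list calls therefore share genes and are not independent, here and against M-CS.

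Osteoblast markers did not move together. The mineral-binding bone sialoprotein IBSP (ENSOCUG00000001046, chromosome 15, 62359429 to 62371843) rose from 24.8 ± 2.02 to 54.2 ± 2.02 CPM (log2 change 1.12, SE 0.11, adjusted p = 1.7e-06). The bone matrix phosphoprotein SPP1 (ENSOCUG00000022536, chromosome 15, 62156546 to 62163822) fell from 283 ± 8.41 to 181 ± 4.93 CPM (log2 change -0.64, SE 0.06, adjusted p = 8.6e-07), as did COL1A1 (ENSOCUG00000012881, chromosome 19, 37474894 to 37582234), from 3783 ± 319.5 to 2602 ± 103 CPM (log2 change -0.54, SE 0.09, adjusted p = 0.00039). BMP2 (ENSOCUG00000011674, chromosome 4, 29449447 to 29450262) did not pass (10.6 ± 0.945 against 8.13 ± 1.152 CPM, adjusted p = 0.095). Over the alternatives its adjusted p ranged from 0.0295, in the comparison with the mean of CS and M-CS, to 0.282. ALPL, SP7 and BGLAP had at most 3 counts in any library and were not tested, and RUNX2 was not analysed here. Of 15 tested members of the osteoblast list, 3 rose, 6 fell and 6 did not pass the test (4 and 7 adjusted over the list alone), with a median log2 change of -0.35, and the list as a whole did not pass (camera adjusted p = 0.069).

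In the lists that did not pass as a whole, counts are given as members higher and lower. BMP and TGF-beta signalling had 3 and 8 of 31 (4 and 9 adjusted over the list alone, camera adjusted p = 0.39). TGFB2 (1.49-fold, adjusted p = 1.8e-05), ACVR1 (1.37-fold, adjusted p = 8.7e-05) and LTBP2 (1.54-fold, adjusted p = 0.00017) were lower. Wnt signalling had 4 and 6 of 24 (6 and 9 adjusted over the list alone, camera adjusted p = 0.61). WNT2 (1.63-fold, adjusted p = 5.8e-05) was higher, and TCF7L2 (1.46-fold, adjusted p = 2e-04) and WISP1 (2.04-fold, adjusted p = 0.00082) were lower. Matrix proteases and inhibitors had 5 and 4 of 26 (9 and 5 adjusted over the list alone, camera adjusted p = 0.1). MMP9 (4.01-fold, adjusted p = 5e-05) was higher, and MMP13 (1.60-fold, adjusted p = 5.5e-05) was lower. Angiogenic factors had 4 and 6 of 23 (6 and 8 adjusted over the list alone, camera adjusted p = 0.56). ANGPTL4 (4.02-fold, adjusted p = 4e-10) was higher, and SEMA3C (1.32-fold, adjusted p = 0.00052) and NRP2 (1.32-fold, adjusted p = 0.0026) were lower. Calcium handling had 4 and 5 of 28 (4 and 5 adjusted over the list alone, camera adjusted p = 0.9). The calcium-regulating hormone STC1 (1.84-fold, adjusted p = 0.0027) was higher, and the channel subunits CACNA2D1 (1.40-fold, adjusted p = 0.0013) and CACNA1G (2.83-fold, adjusted p = 0.0046) were lower. Phosphate and pH transport had 1 and 3 of 16 (2 and 3 adjusted over the list alone, camera adjusted p = 0.67). CA13 (1.26-fold, adjusted p = 0.0036) and SLC16A1 (1.21-fold, adjusted p = 0.0026) were lower. Fatty acid and adipocyte genes had 3 and 2 of 11 (5 and 2 adjusted over the list alone, camera adjusted p = 0.073). The desaturases FADS1 (1.31-fold, adjusted p = 0.00015) and FADS2 (1.30-fold, adjusted p = 0.00045) and G0S2 (2.03-fold, adjusted p = 0.00039) were higher. Stromal surface markers had 0 and 6 of 16 (3 and 6 adjusted over the list alone, camera adjusted p = 0.16). CD44 (1.36-fold, adjusted p = 0.00023), ALCAM (1.86-fold, adjusted p = 0.00038) and VIM (1.32-fold, adjusted p = 0.00053) were lower. Hypoxia and glycolysis genes had 2 and 3 of 26 (3 and 3 adjusted over the list alone, camera adjusted p = 0.71). LDHA (1.41-fold, adjusted p = 2.6e-05) and ENO2 (1.52-fold, adjusted p = 3.5e-05) were higher, and P4HA1 (1.42-fold, adjusted p = 0.00054) was lower. Immediate early genes had 5 and 4 of 22 (6 and 7 adjusted over the list alone, camera adjusted p = 0.73). IER3 (1.64-fold, adjusted p = 6.8e-07) and DUSP5 (1.53-fold, adjusted p = 0.0012) were higher, and NR4A2 (1.28-fold, adjusted p = 0.00032) was lower.

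Integrins and focal adhesion genes had 4 and 5 of 28 (9 and 8 adjusted over the list alone, camera adjusted p = 0.84). ITGA2 (2.96-fold, adjusted p = 0.0028) was higher, and ITGA6 (2.11-fold, adjusted p = 4.3e-05) and CAV1 (1.61-fold, adjusted p = 1.6e-05) were lower. The median of this list was -0.01 and its mean 0.01 on the log2 scale, and its test pointed down. For hypoxia and glycolysis the median was below 0, and the mean (0.02) and the test pointed up. Actin and YAP-SRF targets had 1 and 3 of 20 (2 and 3 adjusted over the list alone, camera adjusted p = 0.73), with CTGF (1.49-fold, adjusted p = 0.0012) and AXL (1.26-fold, adjusted p = 0.004) lower and F3 (1.62-fold, adjusted p = 0.0055) higher. The p53 list had 2 and 5 of 20 (3 and 5 adjusted over the list alone, camera adjusted p = 0.16). SESN2, GADD45A (1.53-fold, adjusted p = 1.7e-05) and TP53INP1 (1.55-fold, adjusted p = 8.8e-05) were lower. Lysosome and autophagy genes had 2 and 2 of 26 (2 and 2 adjusted over the list alone, camera adjusted p = 0.55). CTSS (1.88-fold, adjusted p = 0.0017) was higher, and NPC1 (1.29-fold, adjusted p = 0.00079) and WIPI1 (1.21-fold, adjusted p = 0.008) were lower. Heat shock genes had 0 and 3 of 14 (0 and 3 adjusted over the list alone, camera adjusted p = 0.71). All 3 calls ended with 1 library left out. They were HSPD1 (adjusted p = 0.0528 to 0.0925 without CS replicate 1 or 3 or 5% CBM-CS replicate 1 or 2), CRYAB (adjusted p = 0.0706 to 0.136 without CS replicate 2 or 5% CBM-CS replicate 1, 2 or 3) and BAG3 (adjusted p = 0.0614 to 0.193 without CS replicate 1 or 3, M-CS replicate 2 or 3 or 5% CBM-CS replicate 1, 2 or 3). The cell cycle list had 1 and 0 of 28 (1 and 0 adjusted over the list alone, camera adjusted p = 0.66), its member past the test being RRM2 (1.96-fold, adjusted p = 0.0028), the ribosomal list 1 and 0 of 29 (1 and 0 adjusted over the list alone, camera adjusted p = 0.67), with RPS21 (log2 change 0.32, adjusted p = 0.011), and mitochondrially encoded genes 0 and 0 of 13 (0 and 0 adjusted over the list alone, camera adjusted p = 0.86).

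Markers of other cell types were also measured. Macrophage and monocyte markers had 3 and 1 of 5 (3 and 1 adjusted over the list alone, camera adjusted p = 0.24) members higher and lower. CTSS rose and LAPTM5 (1.46-fold, adjusted p = 0.00021) fell, while CD68 (1.33-fold, adjusted p = 0.021) and CD14 (2.94-fold, adjusted p = 0.035) rose, and the CD68 call was lost (adjusted p = 0.0617 to 0.0766 without CS replicate 1 or 3 or 5% CBM-CS replicate 1 or 2). All 3 tested neutrophil markers, S100A12 (2.50-fold, adjusted p = 7.8e-07), S100A9 (2.18-fold, adjusted p = 0.00091) and S100A8 (2.85-fold, adjusted p = 0.0068), rose, and each was also expressed in CS, S100A8 at 175 ± 41.5 CPM. PTPRC, TYROBP, SPI1, AIF1 and ITGAM, which leukocytes carry in abundance, had at most 2 counts in any library. Of 3 tested endothelial markers, PECAM1 (2.79-fold, adjusted p = 0.002) rose and FLT1 (2.62-fold, adjusted p = 0.00032) fell, while CDH5 and KDR had no count. Smooth muscle and pericyte markers had 1 and 2 of 10 (2 and 2 adjusted over the list alone, camera adjusted p = 0.71), with ABCC9 (1.39-fold, adjusted p = 2.4e-05) and CSPG4 (1.71-fold, adjusted p = 0.011) lower and SMTN higher, a call that was lost (adjusted p = 0.0649 to 0.15 without CS replicate 1 or 3 or 5% CBM-CS replicate 1, 2 or 3). Osteoclast markers had 1 and 0 of 5 (2 and 0 adjusted over the list alone, camera adjusted p = 0.075), the member being MMP9. The lymphocyte list had no tested member, and the erythroid, skeletal muscle and epithelial lists had 1 tested member each, not past the test.

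Of the 33 lists tested, camera called 5 higher and 6 lower, and with an estimated correlation the calls of the NRF2 and metal response and of cholesterol synthesis held in both comparisons of 5% CBM-CS, and no other list call did.

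With edgeR, leaving out CS replicate 3, 5% CBM-CS replicate 1 or 5% CBM-CS replicate 2 lowered the count of 1802 genes to 1187, 1170 and 1120. Without CS replicate 1 it was 1215, with 603 genes lower in place of 905. Scaling by library size alone gave 594 genes higher and 1847 lower, in place of 897 and 905, and shifted the median of all genes by -0.104 on the log2 scale. Limma on FPKM, which are likewise scaled by total count, gave 490 genes higher and 1374 lower. The even balance of rises and falls therefore depended on the scaling. Fry did not call unfolded protein response (adjusted p = 0.057). Library size alone and limma on FPKM also ended the calls of NDUFA2 (adjusted p = 0.0607 and 0.0774), ATP5C1 (0.218 and 0.188) and SMTN (0.0569 and 0.152), and limma that of CD68 (0.0701). DESeq2 ended those of CRYAB (0.0507) and BAG3 (0.0784).

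The comparison of 5% CBM-CS with M-CS set the bacteria medium treatment against a medium treatment of the same scaffold. Cytokines again rose most among genes with at least 5 FPKM in the higher group. IL36G rose from 11.4 ± 0.151 to 198 ± 10.4 CPM (log2 change 4.12, SE 0.08, adjusted p = 1.6e-15), IL36A from 3.44 ± 1.00 to 47.0 ± 2.88 CPM (log2 change 3.78, SE 0.15, adjusted p = 6.2e-11) and IL1B from 6.19 ± 1.18 to 37.4 ± 3.28 CPM (6.05-fold, adjusted p = 1.6e-09). PHGDH (46.1 ± 3.54 against 86.4 ± 5.89 CPM), HMGCS1 (103 ± 2.01 against 167 ± 10.8 CPM) and LOX (1122 ± 27.5 against 1945 ± 59.3 CPM) fell. In the edgeR test 1455 of 11291 genes passed, 742 higher and 713 lower in 5% CBM-CS, 207 of them by at least 2-fold, and 182 without a name. The 3 values of each group did not overlap in 31.8% of tested genes, where chance gives 10%.

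CSF2 rose from 17.5 ± 9.75 to 169 ± 6.06 CPM (log2 change 3.26, SE 0.58, adjusted p = 0.015), IL23A from 31.96 ± 15.7 to 294 ± 7.29 CPM (log2 change 3.19, SE 0.51, adjusted p = 0.0095) and CCL5 from 17.2 ± 8.92 to 109 ± 3.41 CPM (log2 change 2.66, SE 0.54, adjusted p = 0.025). MMP12 (log2 change 2.55, SE 0.12, adjusted p = 7.6e-08) and CYP1A1 (log2 change 2.40, SE 0.11, adjusted p = 1.5e-10) completed the 8 largest rises. Rises and falls were ranked among genes with a symbol, groups that did not overlap and at least 5 FPKM in the higher group. By this rule the largest falls were NCAM1 (log2 change -1.83, SE 0.40, adjusted p = 0.031), ALDH1L2 (log2 change -1.63, SE 0.40, adjusted p = 0.047), the arginase ARG2 (2.87-fold, adjusted p = 4.1e-05) (ENSOCUG00000000584, chromosome 20, 4603540 to 4639377) and SH3BGRL2 (2.71-fold, adjusted p = 7.6e-05). They were followed by the growth factor GDF6 (2.65-fold, adjusted p = 0.019) (ENSOCUG00000008104, chromosome 3, 111889623 to 111907543), TMEM100 (2.56-fold, adjusted p = 1.3e-05), the endothelial lipase LIPG (2.53-fold, adjusted p = 1.5e-09) (ENSOCUG00000013471, chromosome 9, 90453685 to 90473093) and ATP10A (2.45-fold, adjusted p = 2.2e-10) (ENSOCUG00000006386, chromosome 17, 80340543 to 80522603). Leaving out 1 library ended the calls of CSF2 (adjusted p = 0.0512 to 0.0527 without M-CS replicate 3 or 5% CBM-CS replicate 1 or 2) and CCL5 (adjusted p = 0.0596 to 0.0775 without M-CS replicate 2 or 3 or 5% CBM-CS replicate 1, 2 or 3). It also ended those of NCAM1 (adjusted p = 0.0507 to 0.103 without CS replicate 1, M-CS replicate 1 or 3 or 5% CBM-CS replicate 1, 2 or 3) and GDF6 (adjusted p = 0.0575 to 0.0771 without M-CS replicate 2 or 5% CBM-CS replicate 1 or 3). The least stable was ALDH1L2 (adjusted p = 0.0596 to 0.143 without CS replicate 1 or 3, M-CS replicate 1, 2 or 3 or 5% CBM-CS replicate 1, 2 or 3). M-CS replicate 1 had 7.04 CPM of CCL5 where M-CS replicates 2 and 3 had 23.7 and 20.9, and 144 CPM of ALDH1L2 where they had 69.8 and 66.9. Of unnamed genes under the same cuts, ENSOCUG00000027378 (1.92 on the log2 scale) and ENSOCUG00000029216 (1.82) rose most, and ENSOCUG00000000779 (-1.65) and ENSOCUG00000022549 (-1.23) fell most.

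Of the inflammatory cytokines and chemokines, 10 rose, 1 fell and 5 did not pass the test (12 and 1 adjusted over the list alone, median log2 change 0.82), with IL1A (2694 ± 68.4 against 1061 ± 19.1 CPM) and CXCL8 (25689 ± 879 against 10456 ± 1138 CPM) higher and TNFAIP6 lower (adjusted p = 0.00035). As a list, inflammatory cytokines had camera adjusted p = 4.1e-08, and adjusted p = 0.14 with an estimated correlation. Of the bacterial sensing and NF-kB genes, 14 rose, 0 fell and 15 did not pass the test (16 and 0 adjusted over the list alone). As a list, NF-kB genes had camera adjusted p = 1e-07, and adjusted p = 0.14 with an estimated correlation. BIRC3 (2.15-fold, adjusted p = 1.4e-09), IRAK2 (1.91-fold, adjusted p = 2.1e-06) and NFKBIE (1.73-fold, adjusted p = 2e-05) were higher. Of the interferon response genes, 4 rose, 0 fell and 20 did not pass the test (4 and 0 adjusted over the list alone). As a list, interferon genes had camera adjusted p = 0.0023, and adjusted p = 0.54 with an estimated correlation. The members that rose were IRF1 (2.06-fold, adjusted p = 4.2e-05), IRF7 (2.10-fold, adjusted p = 0.00058), PSMB8 (2.39-fold, adjusted p = 0.00068) and OASL (1.59-fold, adjusted p = 0.019). MX1 had 13.3 CPM in M-CS replicate 1 and 38.0 and 39.0 in M-CS replicates 2 and 3, against 36.5 to 37.6 in 5% CBM-CS. Of the NRF2 and metal response genes, 11 rose, 1 fell and 9 did not pass the test (15 and 1 adjusted over the list alone). As a list, NRF2 genes had camera adjusted p = 1.1e-07, and adjusted p = 0.015 with an estimated correlation. GCLM (2.01-fold, adjusted p = 1.6e-05), PRDX1 (1.504-fold, adjusted p = 2.2e-05) and the ferritin light chain FTL (1.39-fold, adjusted p = 5.5e-05) rose, and the zinc transporter SLC39A10 (1.252-fold, adjusted p = 0.02) fell. Of the respiratory chain genes, 1 rose, 0 fell and 17 did not pass the test (1 and 0 adjusted over the list alone), the member being UQCRC1 (1.22-fold, adjusted p = 0.0066). As a list, respiratory chain genes had camera adjusted p = 0.017, and adjusted p = 0.46 with an estimated correlation.

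Of the integrated stress response and amino acid synthesis genes, 1 rose, 15 fell and 11 did not pass the test (1 and 17 adjusted over the list alone, median log2 change -0.45). As a list, integrated stress genes had camera adjusted p = 1e-07, and adjusted p = 0.14 with an estimated correlation. MTHFD2 (1.72-fold, adjusted p = 2.7e-07), PHGDH (1.87-fold, adjusted p = 3.4e-07) and SESN2 (2.07-fold, adjusted p = 8.7e-07) were lower. Of the unfolded protein response genes, 1 rose, 3 fell and 18 did not pass the test (1 and 3 adjusted over the list alone). As a list, unfolded protein genes had camera adjusted p = 0.0025, and adjusted p = 0.54 with an estimated correlation. HERPUD1 (1.40-fold, adjusted p = 0.00016), the sensor ERN1 (1.35-fold, adjusted p = 0.025) and HSPA5 (1.79-fold, adjusted p = 0.035) fell and XBP1 (1.20-fold, adjusted p = 0.048) rose, and leaving out 1 library ended the calls of HSPA5 (adjusted p = 0.0585 to 0.0902 without CS replicate 1 or 5% CBM-CS replicate 1, 2 or 3) and ERN1 (adjusted p = 0.0534 to 0.125 without M-CS replicate 2 or 3 or 5% CBM-CS replicate 2 or 3). HSPA5 had 4503 CPM in M-CS replicate 1 and 2957 and 2943 CPM in M-CS replicates 2 and 3. Of the cholesterol synthesis genes, 1 rose, 11 fell and 7 did not pass the test (1 and 14 adjusted over the list alone). As a list, cholesterol genes had camera adjusted p = 1.8e-07, and adjusted p = 0.015 with an estimated correlation. HMGCS1 (1.62-fold, adjusted p = 1.6e-06) was among those that fell, and HSD17B7 (1.24-fold, adjusted p = 0.024) rose. Of the collagens, 3 rose, 10 fell and 7 did not pass the test (4 and 12 adjusted over the list alone), with COL11A1 (1.67-fold, adjusted p = 2.6e-07) and COL1A2 (1.57-fold, adjusted p = 7.7e-07) lower and COL7A1 (2.32-fold, adjusted p = 3.4e-07) higher. As a list, collagens had camera adjusted p = 0.0025, and adjusted p = 0.23 with an estimated correlation. Of the non-collagen matrix genes, 3 rose, 15 fell and 13 did not pass the test (3 and 17 adjusted over the list alone). As a list, matrix glycoproteins had camera adjusted p = 2.1e-05, and adjusted p = 0.28 with an estimated correlation. LOX (adjusted p = 8.6e-08), POSTN (1.66-fold, adjusted p = 1.2e-06) and FBN1 (1.47-fold, adjusted p = 4.8e-06) were lower. Of the chondrocyte genes, 0 rose, 4 fell and 6 did not pass the test (0 and 4 adjusted over the list alone), among them ACAN (1.49-fold, adjusted p = 5.4e-05), SOX9 (1.53-fold, adjusted p = 0.00088) and SOX6 (adjusted p = 0.043). As a list, chondrocyte genes had camera adjusted p = 0.011, and adjusted p = 0.23 with an estimated correlation.

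Among osteoblast markers, IBSP rose from 23.5 ± 4.30 to 54.2 ± 2.02 CPM (log2 change 1.21, SE 0.11, adjusted p = 1e-06). SPP1 fell from 276 ± 8.76 to 181 ± 4.93 CPM (log2 change -0.61, SE 0.06, adjusted p = 1.8e-06), and COL1A1 fell from 3519 ± 467 to 2602 ± 103 CPM (log2 change -0.44, SE 0.09, adjusted p = 0.0026). BMP2 did not pass (10.6 ± 0.945 against 7.74 ± 0.842 CPM, adjusted p = 0.057), but passed without CS replicate 2 (adjusted p = 0.0371). Over all alternatives its adjusted p ranged from 0.0291 to 0.208. Of the osteoblast list, 3 rose, 5 fell and 7 did not pass the test (4 and 7 adjusted over the list alone, camera adjusted p = 0.13). The other lists that did not pass held WNT2 (1.46-fold higher, adjusted p = 0.00066), WNT5A (1.24-fold higher, adjusted p = 0.00088) and CTNNB1 (1.29-fold lower, adjusted p = 0.00052) of Wnt signalling, ACVR1 (1.41-fold lower, adjusted p = 5e-05), LTBP2 (1.63-fold lower, adjusted p = 5.3e-05) and TGFB2 (1.42-fold lower, adjusted p = 6.3e-05) of BMP and TGF-beta signalling, and ADAMTS5 (1.65-fold higher, adjusted p = 6.4e-06) and MMP13 (1.70-fold lower, adjusted p = 1.8e-05) of the matrix proteases. They also held ANGPTL4 (3.72-fold higher, adjusted p = 9.4e-10) and NRP1 (1.31-fold higher, adjusted p = 0.0017) with NRP2 (1.35-fold lower, adjusted p = 0.0015) of the angiogenic factors, STC1 (1.97-fold higher, adjusted p = 0.0017) with CACNA1C (1.48-fold lower, adjusted p = 0.0032) and CAMK2D (1.245-fold lower, adjusted p = 0.0053) of calcium handling, and CA13 (1.32-fold lower, adjusted p = 0.00089) of pH transport. Further members were FADS1 (1.32-fold higher, adjusted p = 0.00012), FADS2 (1.36-fold higher, adjusted p = 0.00013) and G0S2 (2.02-fold higher, adjusted p = 5e-04) of fatty acid metabolism, LDHA (1.38-fold higher, adjusted p = 6e-05), ENO2 (1.495-fold higher, adjusted p = 6e-05) and NDRG1 (1.74-fold lower, adjusted p = 0.00031) of hypoxia and glycolysis, CD44 (1.45-fold lower, adjusted p = 3.8e-05), VIM (1.37-fold lower, adjusted p = 2e-04) and PDGFRB (1.29-fold lower, adjusted p = 0.0011) of the stromal markers, and ITGA6 (1.97-fold lower, adjusted p = 0.00012), CAV1 (1.47-fold lower, adjusted p = 0.00016) and PXN (1.35-fold higher, adjusted p = 0.0027) of integrins and focal adhesion. Camera adjusted p over these 22 lists ranged from 0.053 to 0.98. Median, mean and test differed in sign for integrins (median 0.02, test down), actin targets (median 0.01, test down), heat shock genes (median 0.06, test down), smooth muscle markers (median 0.05, test down) and hypoxia and glycolysis (median -0.01, test up).

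Counts of members higher and lower in these lists were as follows. Wnt signalling had 4 and 6 of 24 (5 and 7 adjusted over the list alone, camera adjusted p = 0.28). BMP and TGF-beta signalling had 3 and 7 of 31 (5 and 12 adjusted over the list alone, camera adjusted p = 0.076). Matrix proteases had 6 and 5 of 26 (9 and 6 adjusted over the list alone, camera adjusted p = 0.088). Angiogenic factors had 3 and 7 of 23 (5 and 9 adjusted over the list alone, camera adjusted p = 0.36). Calcium handling had 2 and 3 of 28 (2 and 3 adjusted over the list alone, camera adjusted p = 0.92). Phosphate and pH transport had 1 and 3 of 16 (1 and 4 adjusted over the list alone, camera adjusted p = 0.39). Fatty acid genes had 4 and 2 of 11 (5 and 2 adjusted over the list alone, camera adjusted p = 0.053). Hypoxia and glycolysis had 2 and 4 of 26 (3 and 4 adjusted over the list alone, camera adjusted p = 0.98). Stromal markers had 0 and 6 of 16 (2 and 6 adjusted over the list alone, camera adjusted p = 0.13). Integrins had 3 and 6 of 28 (6 and 6 adjusted over the list alone, camera adjusted p = 0.91). Actin targets had 1 and 3 of 20 (1 and 3 adjusted over the list alone, camera adjusted p = 0.98). Immediate early genes had 5 and 4 of 22 (6 and 8 adjusted over the list alone, camera adjusted p = 0.76). The p53 list had 2 and 4 of 20 (2 and 4 adjusted over the list alone, camera adjusted p = 0.082). Lysosome and autophagy had 2 and 2 of 26 (2 and 2 adjusted over the list alone, camera adjusted p = 0.74). Heat shock genes had 0 and 2 of 14 (0 and 2 adjusted over the list alone, camera adjusted p = 0.98). Cell cycle genes had 1 and 0 of 28 (1 and 0 adjusted over the list alone, camera adjusted p = 0.39). Ribosomal proteins had 0 and 0 of 29 (0 and 0 adjusted over the list alone, camera adjusted p = 0.24). Mitochondrially encoded genes had 0 and 0 of 13 (0 and 0 adjusted over the list alone, camera adjusted p = 0.63). Macrophage markers had 1 and 1 of 5 (4 and 1 adjusted over the list alone, camera adjusted p = 0.21). Osteoclast markers had 1 and 0 of 5 (1 and 0 adjusted over the list alone, camera adjusted p = 0.13). Smooth muscle markers had 1 and 2 of 10 (1 and 2 adjusted over the list alone, camera adjusted p = 0.68).

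Of markers of other cells, S100A12 (2.02-fold, adjusted p = 1.2e-05), S100A9 (1.94-fold, adjusted p = 0.0025) and S100A8 (2.29-fold, adjusted p = 0.02) rose, CTSS (1.75-fold, adjusted p = 0.0041) rose, and LAPTM5 (1.32-fold, adjusted p = 0.0031) fell. CD68 and CD14 did not pass (adjusted p = 0.13 and 0.13), and the S100A8 call was lost (adjusted p = 0.0502 to 0.0638 without 5% CBM-CS replicate 1, 2 or 3). All 3 tested endothelial markers passed, with PECAM1 (3.75-fold, adjusted p = 0.00043) higher and FLT1 (2.05-fold, adjusted p = 0.0044) and ERG (0.149 ± 0.182 against 1.07 ± 0.203 CPM, adjusted p = 0.013) lower, and the ERG call was lost (adjusted p = 0.0533 to 0.0748 without M-CS replicate 3 or 5% CBM-CS replicate 1 or 2). ABCC9 (1.40-fold, adjusted p = 2e-05) of the pericyte markers fell.

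**Figure D3:**
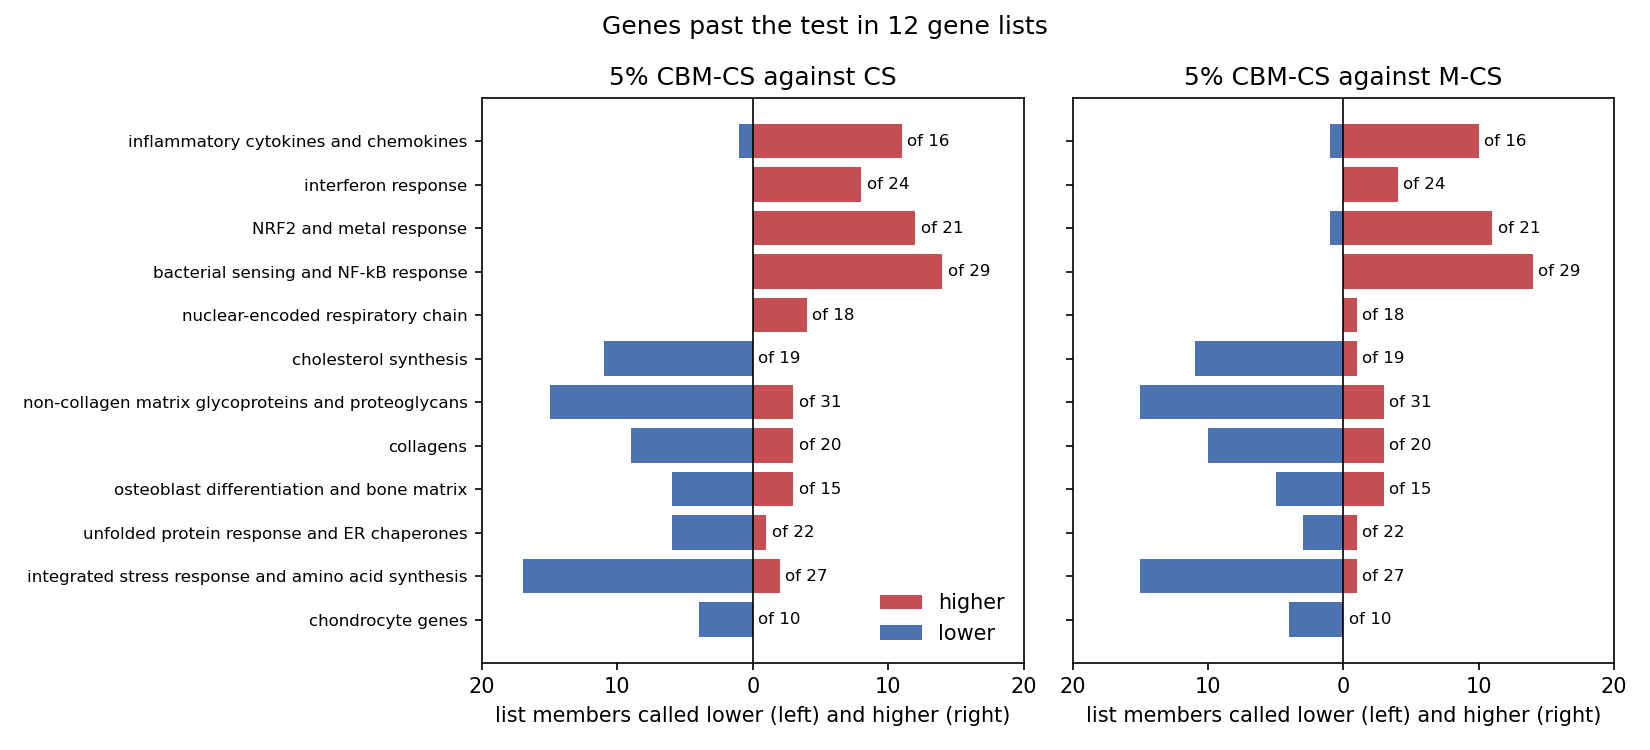
Number of members past the edgeR test in 12 gene lists, lower (left) and higher (right), for 5% CBM-CS against CS and against M-CS, with the number of tested members beside each bar. Of 27 genes of the integrated stress response and amino acid synthesis, 17 were lower against CS and 15 against M-CS.

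With edgeR, leaving out 5% CBM-CS replicate 1 or replicate 2 lowered the count of 1455 genes to 905 and 889, and scaling by library size alone gave 500 genes higher and 1345 lower in place of 742 and 713, and 27.1% higher. Limma on FPKM gave 407 genes higher and 1065 lower. Leaving out M-CS replicate 1 ended the list calls of interferon response (adjusted p = 0.11), unfolded protein response (0.105) and respiratory chain (0.0774), leaving out 5% CBM-CS replicate 1 ended that of chondrocyte genes (0.0732), and library size alone and limma on FPKM ended that of the respiratory chain (0.0994 and 0.0924). Fry did not call interferon response or unfolded protein response (adjusted p = 0.167 each). Leaving out both CS replicate 2 and M-CS replicate 1 ended the list calls of interferon response (0.0952) and respiratory chain (0.0752). Calls of single genes also ended for UQCRC1 with library size alone (adjusted p = 0.0506) and limma on FPKM (0.0729), NRP1 with limma on FPKM (0.0557), and ERN1 with DESeq2 (0.0522). Those of HSPA5 and ALDH1L2 ended without the filter (0.0685 and 0.0625), and that of ALDH1L2 with the 6 libraries alone (0.0716).

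The comparison of M-CS with CS asked what treatment of the scaffold with medium changed. IL36G had means of 11.4 and 10.6 CPM, PHGDH 86.4 and 90.6 CPM, HMGCS1 167 and 165 CPM in M-CS and CS. In the edgeR test 0 of 11291 genes passed (smallest adjusted p = 0.904), and 391 genes (3.46%) had an unadjusted p under 0.05. DESeq2 called 1 gene, ENSOCUG00000006538, which has no name and was higher in M-CS (log2 change 0.31, adjusted p = 0.00224), and limma on FPKM called 0. The 3 values of each group did not overlap in 7.26% of tested genes, where chance gives 10%. IBSP (23.5 ± 4.30 against 24.8 ± 2.02 CPM), SPP1 (276 ± 8.76 against 283 ± 8.41 CPM), COL1A1 (3519 ± 467 against 3783 ± 319.5 CPM) and BMP2 (7.74 ± 0.842 against 8.13 ± 1.152 CPM) did not pass.

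Camera called 4 lists. Interferon response genes were higher in M-CS as a list (median log2 change 0.27, camera adjusted p = 0.0013, and adjusted p = 0.9 with an estimated correlation), as were cytosolic ribosomal proteins (median 0.08, camera adjusted p = 0.0013, and adjusted p = 0.9 with an estimated correlation) and the nuclear-encoded respiratory chain (median 0.08, camera adjusted p = 0.036, and adjusted p = 0.9 with an estimated correlation), and unfolded protein response genes were lower (median -0.16, camera adjusted p = 0.009, and adjusted p = 0.9 with an estimated correlation). No member of these or the other lists passed the edgeR test, and adjusted over the list alone 1 member rose among heat shock genes and 1 among neutrophil markers. The other 29 lists had camera adjusted p = 0.2 to 0.94. Inflammatory cytokines did not pass as a list (median 0.12, camera adjusted p = 0.2), nor did osteoblast genes (median -0.08, camera adjusted p = 0.35). For collagens the median (0.02) and the test, which pointed down, differed in sign, and for fatty acid genes the mean was above 0 and the median and test below it. MX1 ranged from 10.4 to 32.9 CPM in CS and 13.3 to 39.0 CPM in M-CS. HSPA5 ranged from 3040.1 to 4489 CPM in CS and 2943 to 4503 CPM in M-CS. Each of the 6 libraries moved the count of 4 lists, to 0 without CS replicate 1, M-CS replicate 2 or M-CS replicate 3, to 1 without CS replicate 3, to 7 without CS replicate 2 and to 9 without M-CS replicate 1. List calls that ended in this way had adjusted p from 0.0501 to 0.825. That of the respiratory chain also ended without 5% CBM-CS replicate 1 (adjusted p = 0.0533) or replicate 3 (0.0563). In data simulated with the depth of these libraries and a spread estimated from all groups, edgeR found 62% of genes changed 1.5-fold and 86% of genes changed 2-fold. The simulated libraries held no sets that mixed the groups, unlike the CS and M-CS libraries, so these shares cannot tell what was missed here.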

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

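No result called in the main test or in the alternative was reversed. Directions of results called in neither could differ, as for angiogenic factors in 5% CBM-CS against CS (down with camera, up with fry). For 5% CBM-CS against CS, 1802 genes became 264 with an absolute log2 change of at least 1, 931 at adjusted p under 0.01, 1580 with DESeq2, 2441 with library size alone, 1864 with limma on FPKM, and 1120 to 2215 with each library left out. It became 3059 without both CS replicate 2 and M-CS replicate 1. For 5% CBM-CS against M-CS, 1455 became 207, 751, 1288, 1845 and 1472 in the same order, 889 to 1741 with each library left out, and 2191 against the mean of CS and M-CS. In both comparisons, library size alone and limma on FPKM called more genes lower than higher, unlike the main test. For M-CS against CS, 0 genes with edgeR (391 at unadjusted p under 0.05) became 1 with DESeq2, 0 to 0 with each library left out, and 1294 genes and 12 lists without both CS replicate 2 and M-CS replicate 1, which were chosen from their values, so this is no test of M-CS. Scaling with DESeq2 size factors, the filters, the 6 libraries alone and the replicate block moved no gene count by over 1.5-fold. List counts of 11, 11 and 4 became 2, 2 and 0 with an estimated correlation, 17, 16 and 0 with fry, which lost 1 and 2 of the 11 calls in the first 2 comparisons, and 11 to 12, 10 to 13 and 0 to 9 with each library left out. The cause was not tested. Of named results, 91 of 103 against CS, 80 of 98 against M-CS and 3 of 4 for M-CS against CS stayed the same throughout, apart from the 2 stricter thresholds. Most named genes were chosen for a large change or a small p in these same libraries, so these shares do not describe the called genes in general. BMP2 against M-CS (adjusted p = 0.057) passed with the 6 libraries compared (0.0465) and the replicate block (0.0364). Pseudocounts of 0.1 and 0.01 were not applicable because the main test is on counts. With 10.6 M to 12.82 M counts per library and 3 libraries per group, changes under 1.5-fold were often missed in the simulation.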

Other observations

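The genes in this paragraph were chosen after their values were seen. Several genes of inflammation were among the most abundant transcripts of all. In 5% CBM-CS the acute-phase protein SAA3 (44395 ± 2629 CPM against 27036 ± 5133 in CS and 30244 ± 4101 in M-CS), CXCL8 (25689 ± 879 CPM against 9515 ± 929 in CS and 10456 ± 1138 in M-CS), IL6 (14044 ± 349 CPM against 8163 ± 1499.7 in CS and 8861 ± 1199.8 in M-CS) and the prostaglandin synthase PTGS2 (14907 ± 337 CPM against 10689.6 ± 454 in CS and 10607 ± 307 in M-CS) were higher than in both other groups. The collagenase MMP1 (11388 ± 44.7 CPM against 3044 ± 817 in CS and 3665 ± 758 in M-CS) and stromelysin MMP3 (10688 ± 295 CPM against 3025 ± 734 in CS and 3523 ± 663 in M-CS) were too. Other genes higher against CS and against M-CS were the phosphate-regulating hormone FGF23 (log2 change 2.01 and 2.27), SERPINB2 (log2 change 2.44 and 2.22) and the adhesion molecule SELE (log2 change 2.14 and 2.06).

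The first pattern is the grouping of CS replicate 2 with M-CS replicates 2 and 3, and of M-CS replicate 1 with CS replicates 1 and 3. All 3 tests of it were chosen after it was seen, and the design gives no biological explanation that was tested. If the labels of CS replicate 2 and M-CS replicate 1 had been exchanged, each would correlate more with the other group than with its own, and the smallest margin was 0.00367, above 0. An unrecorded batch holding 3 of the 6 libraries could give the same grouping. The 5% CBM-CS libraries spread over 0.0794 of the distance between the 2 sets, which would speak against a batch only if those libraries had been divided between the batches, and the labels do not say. A batch and an exchange of labels cannot be told apart here. Thinning all libraries to the smallest total left the smallest margin at 0.00365, which decides nothing because the totals differ little. In 5 pairs of libraries across the 2 sets the totals differed by less than 0.446 M. CS replicate 2 (11.79 M) and CS replicate 3 (11.8 M), for example, fell in different sets, which argues against library size as the cause. The highest correlation of the 5 pairs, 0.9874, lay 0.00318 below the lowest within the sets, 0.9906. Because the sets were drawn from these correlations, this gap was fixed beforehand and adds nothing.

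The groups were analysed as labelled. If the labels were exchanged, the 0 genes called by edgeR between M-CS and CS could hide an effect of the medium, and the changes of 5% CBM-CS against M-CS would be smaller for genes such as CSF2 and larger against CS. This is a hypothesis that the labels cannot settle, and the smallest margin of 0.00367 came from the same libraries that raised it.

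The second pattern is the rise of inflammatory genes in 5% CBM-CS. The scaling test was written before its result was seen. The leukocyte test was set after values had been seen, because a first bound on all leukocyte markers under 1 CPM in CS and M-CS left the question open through CD14, at 1.71 CPM in 5% CBM-CS. Leukocytes among the cells would bring their abundant transcripts, and the highest of 6 measured, CD74, had a mean of 0.113 CPM. That argues against leukocytes as the source but does not exclude them. TYROBP, AIF1, SPI1 and ITGAM had no count in any library, so it is not shown that they could be detected here. Other genes of myeloid cells did rise against CS. They included CTSS, CD68, CD14, S100A8, S100A9, S100A12 and VSIG4, the last from 2.18 to 15.04 CPM (edgeR adjusted p = 8.3e-06), and of them CD14 had a mean under 1 CPM in CS. Scaling driven by a few abundant genes was tested only through the choice between TMM and library size. That choice did not account for most of these calls. With library size alone a share of at least 0.917 of the called members of the 2 inflammatory lists were still called higher (23 of 25 against CS and 22 of 24 against M-CS).

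The design gives a biological explanation, the treatment with bacteria medium, and how it could act on these genes was not tested. The share of 0.917 shows only that the calls outlast a change of scaling. No group received bacterial products by themselves, and a difference in handling between 5% CBM-CS and the other groups was not tested.

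The last pattern is the rise of CYP1A1, 6.73-fold against CS and 5.29-fold against M-CS. CYP1A1 is a target of the aryl hydrocarbon receptor, which binds some bacterial metabolites, and higher activity of the receptor would raise its other targets. The test in its present form was set after results had been seen, since NQO1, a member of the NRF2 list, was first among its genes and was taken out later. Higher activity was to raise more than 0.5 of the tested targets in both comparisons. Of 5 other targets looked for, 2 were tested and 1, CYP1B1, was higher in both comparisons (log2 change 0.58 and 0.59, edgeR adjusted p = 2.4e-06 in each), whereas TIPARP did not pass (adjusted p = 0.3 and 0.13). That is 1 of 2, which does not reach the bound, and with NQO1 it would be 2 of 3. With so few targets the test could not decide, and the explanation was left open.

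Of the tests by exchange of labels, those of the 2 comparisons with 5% CBM-CS were written before their results and those of M-CS with CS after. With 3 against 3 libraries there are 10 splits, so a share under 0.05 is impossible. For 5% CBM-CS against CS the labelled split called 1802 genes and the highest other 0, so 1 of 10 splits reached it, and 11 lists against at most 8, again 1 of 10. For 5% CBM-CS against M-CS it called 1455 genes against 0 and 11 lists against at most 7, 1 of 10 splits for each. In these 2 comparisons every other split mixed 5% CBM-CS libraries with those of the other group. Any difference between the groups then widens the spread within them, so the 0 genes called do not measure what chance would give. For M-CS against CS edgeR called 0 genes, which all 10 splits reached, and the highest other split called 2069. That split exchanged M-CS replicate 1 and CS replicate 2, and so many genes point to a structure of the samples. For lists, 3 of 10 splits reached the 4 called, and the same split called 13.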
